A study of Mus musculus with 16 samples.

How the data were processed

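Acetylated RNA was immunoprecipitated from the livers of male db/db mice and lean control mice and sequenced. N4-acetylcytidine (ac4C) is a modified cytidine laid down by the enzyme NAT10, and the antibody pulls down RNA fragments that carry it. Per the labels' protocols, ribosomal RNA was depleted, the RNA was broken into short fragments, and libraries were made from the immunoprecipitate and from the input with a kit that keeps strand. The series has 16 samples, of which 8 are immunoprecipitates and 8 are inputs, 4 of each per group. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.3 and aligned to mm10 with HISAT2 2.0.4.

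The values analysed were 8 peak lists, 4 of db/db and 4 of lean mice, each under a name of its own. Whether samples were pooled before calling is not given in the sources used here. Peak names in the deposited lists name MACS as the caller, and its version is not given in the sources used here. Whether the paired input served as the control of the call is also not given there. For each peak the authors gave a score, which equals -10 times the decimal logarithm of the p-value in every row. The fold enrichment in the deposited lists is a linear ratio of immunoprecipitate to background at the peak. The false discovery rate was deposited by the authors in percent. The width of each peak was deposited in base pairs and equalled its end minus its start in every row. No read counts per peak and no totals per library were used here, so sequencing depth is unknown and no counting interval is given for a peak. The lowest score was 13.02 and the lowest fold 2.0, which are taken as the thresholds of the authors' calls. A false discovery rate of 100% stood beside 99.21% of the 68356 peaks, and 1 peak had a rate of 5% or less.

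The lists carry the names db1, db2, db4 and db5, and C5 to C8. These were mapped to the db/db and lean groups but not to numbered samples, because db5 and C5 to C8 do not occur among the sample titles. C was taken to stand for the lean control group, the only other group. The labels number the samples within a group without saying that each is a separate animal. Lists are called mice here, and p-values measure the spread between these samples, which may be technical in part. A gene counted once per mouse however many peaks it had. A score or fold is the authors' own value for a peak and served only to describe or rank peaks within a list and to filter peaks. Filters on score or fold used the same cutoff in every list, although the depth of the lists is unknown. Between lists only the presence or absence of a peak was compared. Absence means that the caller reported no peak, which depends on the depth and transcript level of that mouse as well as on acetylation.

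Peaks of all lists were merged into regions where they shared at least 1 bp. Strand was not given in the lists, so overlapping genes on opposite strands were not separated. Group means were compared by an exact two-sided permutation test over all 70 arrangements of 4 against 4, whose smallest p is 0.0286. Numbers of group-specific genes and regions, present in every mouse of 1 group and in no mouse of the other, were set against the 35 splits of the 8 lists into 4 and 4. The Jaccard index of base pairs was compared within and between groups, one-sided, over the same splits. Each gene was also tested with Fisher's exact test and Benjamini-Hochberg adjustment. Before the data were examined, 27 gene lists were fixed, of which 18 were pathways and 9 cell types. Members with a peak per mouse were compared by the exact permutation test with Benjamini-Hochberg adjustment over the lists. Fisher's exact test asked whether list members were frequent among genes with a peak in at least 3 mice of 1 group and at most 1 of the other, against the 8602 genes with any peak. Of 420 distinct list genes, 419 had their symbol in the RefSeq table of assembly GRCm38.p6, and 245 had a peak. The adjustment also ran over each list alone.

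The genes named were chosen by a rule fixed before the data were examined. It took Nat10 and Srebf1, then 12 genes per direction among group-specific genes, ordered by the mean percentile of their best fold within each list and without predicted genes. From each list it took up to 4 members whose number of mice with a peak differed most, by at least 2. Some genes that the rule selects are not reported here. Gene identifiers of 98.03% of peaks matched the RefSeq table, and 99.6% of matched peaks overlapped the bounds of their gene. Those bounds are of the same build as the peaks. Exon, intron and untranslated region annotation and the genome sequence were not used here, so the planned tests of position in the transcript and of cytidine content were not run. Enrichment of the functional terms in the lists (terms of 10 to 500 genes, hypergeometric test, Benjamini-Hochberg adjustment) was added after the data had been examined, as were a peak score of at least 50 (the MACS default p of 1e-05), the share of peaks near gene ends with its alternatives and those tests that the closing section names as chosen then.

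Alternatives fixed beforehand were the upper part of the pooled score, a fold of at least 4, equal numbers of peaks per list, autosomes alone, each list left out in turn, other overlap rules, other definitions of group-specific, and predicted genes left out. The gene comparison was tested on simulated data with 8602 genes, of which 200 were changed. Changed genes were given a fixed high chance of a peak in 1 group and a fixed low chance in the other, drawn independently for each mouse. In 20 simulations 66.5% of changed genes were recovered against 66.3% implied by these settings, with a mean of 20.2 unchanged genes called. The match checks the counting and does not measure the power to find changes in the real lists. Analyses used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.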

Results

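Acetylated RNA was mapped in the livers of db/db mice, which lack a working leptin receptor and become obese and diabetic, and of lean controls. Peak lists of 4 mice per group were analysed, 68356 peaks in all, falling in 8602 genes. The 4 db/db lists held 8878, 9267, 9754 and 8212 peaks (db1, db2, db4 and db5), and the 4 lean lists held 8503, 8066, 8093 and 7583 (C5 to C8). Peaks were found in all 8 mice in 1701 genes (19.8%), and in a single mouse in 1981 genes. Of 25437 merged regions, 1579 (6.21%) were called in all 8 mice and 11456 (45.0%) in 1 mouse.

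The first question was whether the livers of db/db mice carry more acetylated sites. Lists of db/db mice averaged 9028 ± 651 peaks (SD, n = 4) and lists of lean mice 8061 ± 376, a difference of 966.5 peaks that missed the threshold (exact permutation p = 0.0571). Genes with a peak numbered 4671 ± 269 in db/db and 4355 ± 234 in lean mice, which did not differ by the exact permutation test (p = 0.2). With equal numbers of peaks taken from each list the difference in genes turned to -21.5 (exact permutation p = 0.83). Without the db5 list the difference in peaks was 1238 and passed (exact permutation p = 0.0286). At a fold of at least 4 the difference in peaks was 400.5 (exact permutation p = 0.114). It was 285.2 in the upper part of the pooled score (exact permutation p = 0.2). Among peaks with a score of at least 50 it was 103.2 (exact permutation p = 0.514).

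**Figure D1:**
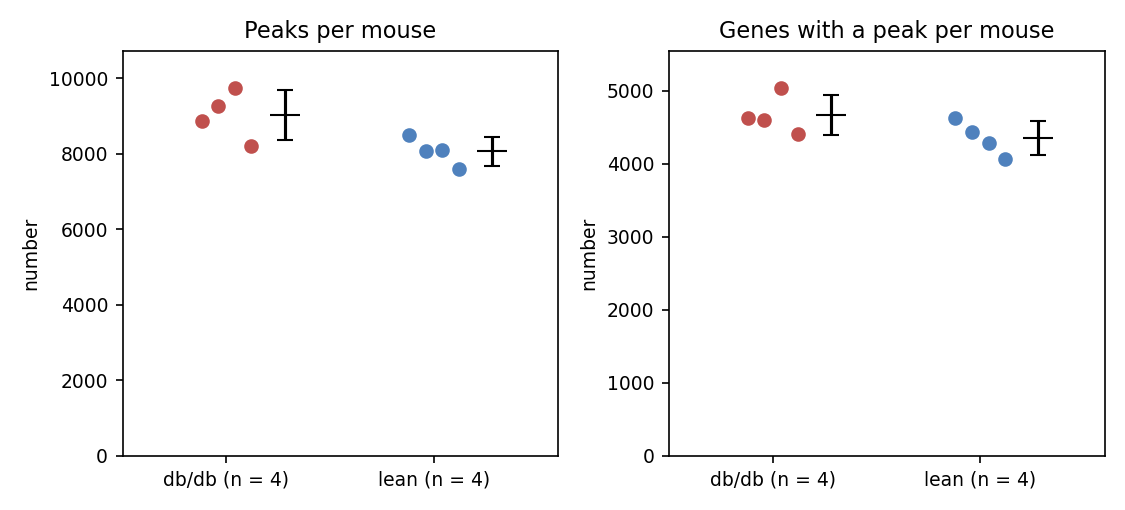
Number of peaks (left) and number of genes with a peak (right) in each of 4 db/db and 4 lean mice. Points are mice, and bars to their right are the mean and SD; db/db lists reach from 8212 to 9754 peaks and lean lists from 7583 to 8503.

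Nat10, which encodes the ac4C writer, had a peak in 3 of 4 db/db and 3 of 4 lean mice. Its most unequal region, on chromosome 2 from 103721256 to 103721928 (mm10), was called in 1 db/db mouse at a fold of 3.5 and in 3 lean mice at folds of 3.55 to 7.57. The gene runs from 103721258 to 103762954. Srebf1, the transcription factor that drives fatty acid synthesis genes, had peaks in 1 db/db mouse and no lean mouse. Its region on chromosome 11 from 60199092 to 60200151 had a fold of 9.37. Among 12 fixed genes of the ac4C writer and its nucleolar partners, 9.25 ± 0.957 had a peak per db/db mouse and 8.25 ± 1.26 per lean mouse (n = 4 each, exact permutation p = 0.4). Nop58, Ncl and Nolc1, genes of nucleolar proteins, had a peak in all 8 mice. Utp15 and Nop2 had one in 3 db/db and 1 lean mouse each.

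A peak in every db/db mouse and no lean mouse was found in 81 genes. Nr5a2, a nuclear receptor that controls bile acid synthesis, had such peaks on chromosome 1, with a region from 136944959 to 136945077 in all 4 db/db mice at folds of 4.76 to 7.17. The gene spans 136842562 to 136960448. Nfil3, a transcriptional repressor linked to the circadian clock, had 1 region, on chromosome 13 from 52980861 to 52981073, at folds of 4.76 to 11.24. In Sulf2, an enzyme that removes sulphate from heparan sulphate, the region on chromosome 2 from 166093455 to 166093624 had folds of 3.4 to 5.36. Naf1, an assembly factor of small nucleolar RNA particles, was called on chromosome 8 from 66860217 to 66861046 at folds of 3.41 to 7.96. The region of Vps37b, a part of the endosomal sorting machinery, lay on chromosome 5 from 124032102 to 124032260. It ended at the annotated end coordinate of the gene, whatever its strand. The other genes named by the fixed rule were Efcab2, Inadl (a tight junction scaffold), Acpp, Ppl (a desmosome protein), Mgmt (a DNA repair enzyme), Mapre1 (a microtubule end-binding protein) and Cgref1.

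A peak in every lean mouse and no db/db mouse was found in 58 genes. The direction of the excess turned with equal numbers of peaks per list, to 58 db/db-specific and 70 lean-specific genes, and at a score of at least 50, to 28 and 34. In the upper part of the pooled score the numbers were 53 and 53, and at a fold of at least 4 they were 53 and 47. Sf3b4, a core splicing factor, had its region on chromosome 3 from 96176979 to 96177564 at folds of 5.82 to 14.71, up to the annotated end coordinate of the gene. Eif5, a translation initiation factor, was called on chromosome 12 from 111539031 to 111539687 at folds of 5.56 to 7.38. Gbe1, the glycogen branching enzyme, had a region on chromosome 16 from 70313949 to 70314295 at folds of 3.56 to 10.2, which began at the annotated start coordinate of the gene. Bco1, which cleaves beta-carotene to retinal, was called on chromosome 8 from 117132974 to 117133711 at folds of 4.23 to 7.77. Lactb, Rhbdd3, Catsper2 (a sperm ion channel subunit), Dnali1 (an axonemal dynein chain) and C1s2 (a complement protease gene with a close paralog) completed the protein-coding genes of the rule. Rps18-ps3, Rps2-ps6 and Tpm3-rs7 are pseudogenes, so reads of their parent genes can be placed on them and their calls are uncertain. Rps18-ps3 had the highest folds of these lean-specific genes, 12.74 to 21.47.

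The 139 group-specific genes exceeded the number in each of the other 34 splits of the 8 lists, which gave 9 to 32 (median 17). For a single gene the design allows only weak evidence. A pattern of 4 against 0 has an exact Fisher p of 0.0286, the smallest the design allows. After Benjamini-Hochberg adjustment 0 of 8602 genes passed (smallest adjusted p 1.0), against 139 at an unadjusted p under 0.05. A pass would need 57.1% of the genes at 4 against 0, so this outcome says nothing about the genes. Of 31 named genes with 4 against 0 mice, 18 kept that pattern at a fold of at least 4. It was kept by 14 in the upper part of the pooled score and by 5 at a score of at least 50. These checks on named genes were chosen after the data had been examined. The rule took 12 genes per direction for their high fold, so these numbers do not describe group-specific genes at large. Acaa2, Atp5a1, Cdh1, Icam1, Insr, Lpin1 and Timd4, named through gene lists, lost the pattern at that fold.

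**Figure D2:**
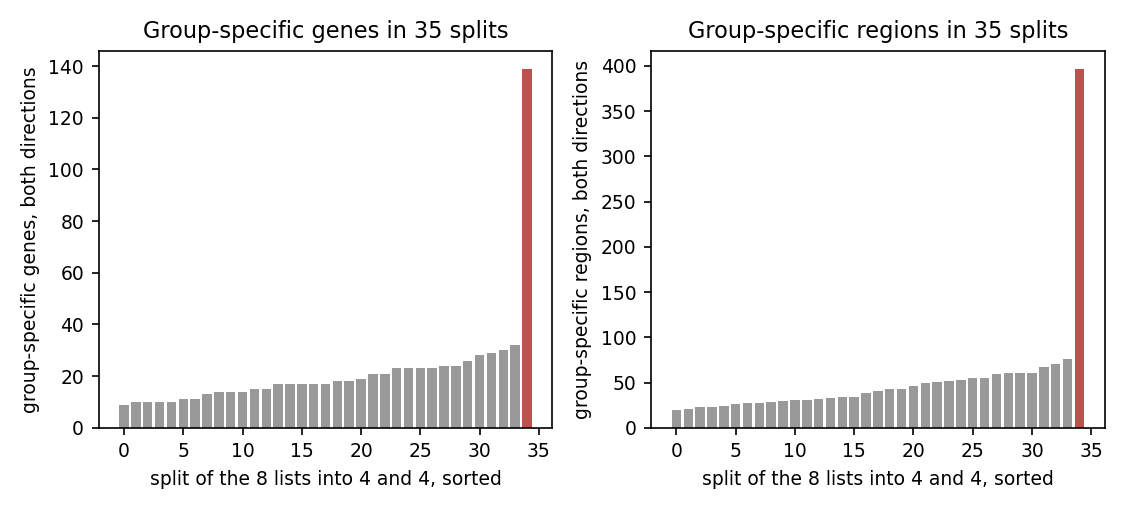
Genes (left) and regions (right) with a peak in 4 mice of 1 set and none of the other, both directions added, for each of the 35 splits of the 8 lists into 4 and 4, sorted on the horizontal axis. The split into db/db and lean (red) gives 139 genes and 397 regions, against at most 32 genes and 76 regions in the others (grey).

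Regions were compared because a gene can keep a peak at 1 site and lose it at another. There were 217 regions called only in all 4 db/db mice and 180 only in all 4 lean mice, a total of 397 against 20 to 76 in the other splits (median 39.5). With equal numbers of peaks per list there were 155 db/db and 182 lean regions. Of the 217 db/db regions 166 lay in genes that were not group-specific themselves, as did 137 of the 180 lean regions. Pik3ca, the catalytic subunit of a kinase in insulin signalling, is an example. Its region on chromosome 3 from 32397671 to 32397800 was called in all 4 lean mice and no db/db mouse, while 2 db/db mice had a peak elsewhere in the gene. Eif2ak3, the endoplasmic reticulum stress kinase, had the opposite pattern on chromosome 6 from 70882265 to 70882427, in 4 db/db mice and no lean mouse, with a peak of the gene in 2 lean mice.

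Peak sets of mice of the same group were more alike than those of different groups. The Jaccard index of base pairs averaged 0.362 over 12 pairs within groups (0.306 to 0.384) and 0.297 over 16 pairs between groups (0.271 to 0.325). The difference of 0.0652 was the highest of 35 splits (one-sided permutation p = 0.0286, the smallest they can give). Lean mice resembled each other more (mean 0.378) than db/db mice did (mean 0.347), a difference that was not tested. The db1 list had a mean index of 0.319 with the other db/db lists, against 0.350 to 0.363 for db2, db4 and db5.

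Genes of fat synthesis leaned in both directions, with 5 members in at least 3 db/db and at most 1 lean mouse and 3 members the other way, neither enriched after adjustment. Lpin1, which makes the diacylglycerol used for triglycerides, had a peak in 4 db/db and no lean mice, with a region on chromosome 12 from 16565391 to 16565697 at folds of 2.66 to 6.65. Its difference of 100 percentage points fell to 75 with equal numbers of peaks, 50 at a fold of at least 4, and 25 in the upper part of the pooled score and at a score of at least 50. Elovl6, Fads2 and Acly, genes of fatty acid elongation, desaturation and cytosolic acetyl-CoA supply, had peaks in 3 db/db and no lean mice. Elovl5 (0 db/db and 3 lean mice), Agpat2 (1 and 4) and Me1 (1 and 3) had the opposite lean, and are named outside the rule, after their values had been seen. The whole list did not pass, with 11 ± 4.32 of 21 genes per db/db mouse and 9.25 ± 2.5 per lean mouse (n = 4 each, exact permutation p = 0.543). The db1 mouse had 5 of these genes, against 11 to 15 in the other db/db mice. Leaving out each list in turn gave differences of 0.417 to 3.75 genes. Fatty acid uptake and lipid droplet genes stood at 5.5 ± 3.79 and 5.25 ± 2.06 of 24 (exact permutation p = 1.0), with 11 in db1 against 3 to 5 in the other db/db mice. Cidea, a lipid droplet protein, had a peak in 2 db/db mice. Cholesterol synthesis and uptake genes averaged 8.0 ± 3.83 and 7.25 ± 0.957 of 20 (exact permutation p = 0.857). Dhcr7 and Idi1 had a peak in 2 db/db mice each.

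Fatty acid oxidation and ketogenesis had a lower mean in db/db mice, 4.75 ± 1.5 against 6.75 ± 0.957 of 22 genes (n = 4 each, exact permutation p = 0.171), and the difference turned to 0.25 at a fold of at least 4. Acaa2, a thiolase of mitochondrial beta-oxidation, had peaks in no db/db and 4 lean mice. Hadha, another enzyme of that pathway, and Ppargc1a, a coactivator of mitochondrial genes, had peaks in 2 db/db and 4 lean mice. In the upper part of the pooled score the difference for Ppargc1a turned to 50 percentage points, with more db/db mice. Oxidative phosphorylation genes had a peak in 1.25 ± 1.26 of 18 per db/db mouse and 3.5 ± 1.0 per lean mouse (exact permutation p = 0.114), and the difference of -2.25 shrank to -0.75 at a fold of at least 4. Atp5a1, a subunit of ATP synthase, was called in 0 db/db and 4 lean mice, and Atp5c1 and Uqcrc1 in 2 and 4. Ribosomal protein genes stood at 2.0 ± 0.816 and 4.0 ± 0.816 of 22 (exact permutation p = 0.0571), with Rpl32 in 0 and 3 mice and Rps3 and Rpl8 in 2 and 4. The ribosomal difference was -2.75 in the upper part of the pooled score, -2.25 at a fold of at least 4 and -2.75 at a score of at least 50. Each had an exact permutation p of 0.0286, and their adjusted p were 0.386, 0.771 and 0.771. Acaa2 and Atp5a1 had no peak with a fold of at least 4 in any mouse.

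Genes of bile acid synthesis and transport had a peak in 4.75 ± 2.5 of 16 per db/db mouse and 1.5 ± 1.29 per lean mouse (n = 4 each, exact permutation p = 0.114). Abcg8 and Abcg5, the paired sterol exporters, were called in 3 db/db mice each and in 0 and 1 lean mice. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and Cyp7b1 were called in 2 db/db mice and no lean mouse. Xenobiotic metabolism genes averaged 4.25 ± 1.71 and 2.0 ± 0.816 of 17 (exact permutation p = 0.114), with Cyp1a2 and Cyp2b10 in 3 db/db and no lean mice. Without the db1 list the exact permutation p was 0.0286 for the differences in bile acid (4.5 genes), xenobiotic (3.0) and secreted plasma protein genes (-2.42), each with an adjusted p of 0.193. At a score of at least 50 the bile acid difference of 3.25 shrank to 0.25, with that of Abcg8 at 0 and that of Abcg5 at -25 percentage points. The xenobiotic difference of 2.25 shrank to 1.0 and the plasma protein difference of -1.5 to -0.5 at a fold of at least 4. Antioxidant defence genes stood at 5.25 ± 0.957 and 3.0 ± 2.16 of 16 (exact permutation p = 0.143), with Cat, which encodes catalase, in 3 db/db and no lean mice and Gclc in 2 and none.

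Glucose metabolism genes averaged 4.5 ± 0.577 of 16 in db/db and 2.25 ± 2.06 in lean mice (n = 4 each, exact permutation p = 0.143). Pfkl, the liver phosphofructokinase, was called in 4 db/db and 1 lean mouse, the glucose transporter gene Slc2a2 in 3 and 1, and Pcx, pyruvate carboxylase, in 2 and 0. The difference of 2.25 glucose metabolism genes shrank to 0.5 at a fold of at least 4, where Pfkl, Slc2a2 and Pcx had a difference of 0 percentage points each. Insulin and leptin signalling genes stood at 11.5 ± 2.38 and 10.5 ± 1.0 of 19 (exact permutation p = 0.743). Insr, the insulin receptor, had a region on chromosome 8 from 3279029 to 3279617 in all 4 lean mice at folds of 3.08 to 3.31, and no peak in db/db mice. All Insr folds were under 4. Irs2, Pik3r1, Akt1 and Mtor had a peak in all 8 mice. Igfbp2 was called in 3 db/db and 1 lean mouse.

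Inflammation and acute phase genes averaged 5.75 ± 1.71 and 4.75 ± 0.5 of 21 in db/db and lean mice (n = 4 each, exact permutation p = 0.514). Icam1, an adhesion molecule of leukocyte entry, was called in 4 db/db and no lean mice, Jun in 4 and 2, and Nfkbia in 2 and 0. Fibrosis and matrix genes stood at 9.75 ± 1.71 and 9.0 ± 0.816 of 20 (exact permutation p = 0.686). Spp1 and Acta2 were called in 2 db/db mice only, and Col1a2 and Pdgfrb in 2 lean mice only. Endoplasmic reticulum stress genes averaged 9.5 ± 2.52 and 10.2 ± 1.26 of 20 (exact permutation p = 0.771), with the chaperone Calr and Sdf2l1 in 1 db/db and 3 lean mice. Secreted plasma protein genes stood at 1.25 ± 1.89 and 2.75 ± 0.5 of 24 (exact permutation p = 0.229), with Apoa4 in 1 and 4 mice, Plg in 1 and 3, and Ambp in 0 and 2. Circadian clock genes averaged 7.5 ± 2.08 and 6.0 ± 1.63 of 16 (exact permutation p = 0.371), with Cry1 in 3 and 1 mice and Hlf in 2 and 0. Autophagy and lysosome genes averaged 5.25 ± 1.26 and 4.5 ± 1.0 of 16 (exact permutation p = 0.543), with Tfeb in 2 and 0.

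Among cell type markers, those of stellate cells and fibroblasts had a peak in 6.0 ± 1.41 of 12 per db/db mouse and 3.25 ± 1.5 per lean mouse (n = 4 each, exact permutation p = 0.0286). This was the only list with an unadjusted p under 0.05, and its adjusted p over 27 lists was 0.551. Colec10 was called in 4 db/db and 1 lean mouse, Des in 3 and 0, Hgf in 3 and 1, and Rgs5 in 2 and 0, while Pdgfrb was called in 0 and 2. The list's difference turned to -0.5 at a fold of at least 4 and to -0.75 at a score of at least 50. Hepatocyte markers averaged 1.75 ± 1.5 and 0.25 ± 0.5 of 12 (exact permutation p = 0.257), with Hnf4a in 3 db/db and 1 lean mouse and Cps1 in 2 and 0. Kupffer cell and macrophage markers stood at 2.25 ± 1.26 and 2.5 ± 1.0 of 15 (exact permutation p = 1.0). Timd4, a marker of resident Kupffer cells, was called in 4 lean and no db/db mice, Marco in 4 db/db and 2 lean mice, and Cd5l in 2 db/db mice.

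Sinusoidal endothelial markers averaged 5.75 ± 2.06 and 5.75 ± 1.89 of 12 in db/db and lean mice (n = 4 each, exact permutation p = 1.0). Stab1 was called in 3 db/db and 1 lean mouse, and Tek, Lyve1 and Egfl7 in more lean mice (0 and 3, 1 and 3, 2 and 4). Cholangiocyte markers stood at 2.25 ± 1.5 and 1.75 ± 0.5 of 8 (exact permutation p = 0.743), with Cdh1 in 4 lean and no db/db mice and Epcam in 2 db/db mice. At a score of at least 50 the differences of Cdh1 and Epcam were 0. Lymphocyte markers averaged 1.25 ± 0.957 and 0.25 ± 0.5 of 11 (exact permutation p = 0.257), with Cd74 in 3 db/db and no lean mice and Ptprc in 2 and 0. Neutrophil, erythroid and adipocyte markers had at most 1 gene with a peak in any mouse, with an exact permutation p of 1.0 each.

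Over the 27 lists, 19 had a higher mean in db/db, 6 a lower mean and 2 the same mean, and 0 passed the exact permutation test after Benjamini-Hochberg adjustment. With 4 mice per group 16 lists would have to reach the smallest p at once for any to pass, so this outcome says little. Fisher's exact test found 0 of 54 combinations of list and direction enriched (smallest adjusted p 0.596). No list gene passed when adjusted over the list alone (0 genes), which needs 57.1% of a list's tested members at 4 against 0 and so says nothing about the members. With equal numbers of peaks per list 0 lists had an unadjusted p under 0.05. Differences of cholesterol (-0.5), fibrosis (-0.75), circadian clock (-0.25) and autophagy genes (-0.25) changed sign in that setting.

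**Figure D3:**
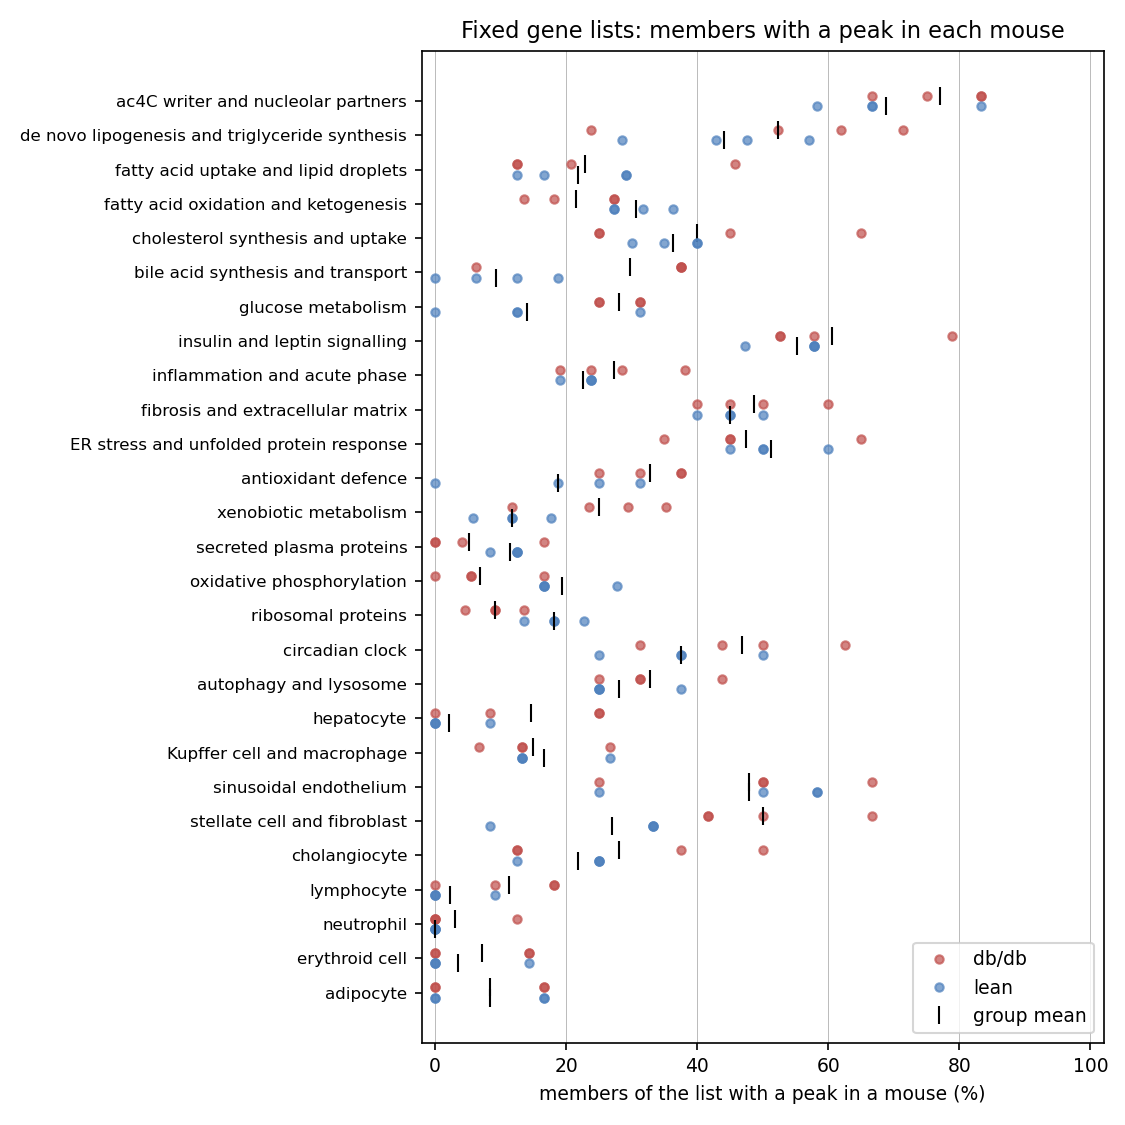
Share of the members of each fixed gene list with a peak (horizontal axis, percent), for 4 db/db mice (red) and 4 lean mice (blue); points are mice and vertical ticks are group means. The groups overlap in most lists, and stellate cell and fibroblast markers (6.0 against 3.25 of 12 genes) have the only unadjusted p under 0.05.

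The median width of a peak was 178 ± 1.5 bp in db/db lists and 188 ± 5.12 bp in lean lists (n = 4 each), and every lean list (183 to 195 bp) was above every db/db list (177 to 180 bp). The authors' median fold was 4.05 ± 0.0294 in db/db and 4.09 ± 0.065 in lean lists. A score of at least 50 was reached by 30.9 ± 2.67% of db/db peaks and 33.2 ± 1.47% of lean peaks. These values describe each list and were not tested between groups.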

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

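The test of a transcript level that differs between groups and that of an absent transcript were set before their results were seen. The test on weak peaks and the split test on genes were chosen after the data had been examined.

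Among 69 sets of 4 mice, 14 held a value far from the other 3 by Dixon's test, where chance gives about 3.5. Most of the 14 are small whole numbers: 13 come from gene lists, and 7 of these lie 1 gene from the other mice, where ties make such a gap common. The db1 mouse had 1 gene of bile acid synthesis and transport with a peak, against 6 in each other db/db mouse, and 1 neutrophil marker against 0. The C5 mouse had 112 peaks with a false discovery rate under 100%, against 60 to 67 in the other lean mice. C5 also had 4 inflammation genes against 5, 2 secreted plasma protein genes against 3 and 1 cholangiocyte marker against 2. The C6 mouse had 5 oxidative phosphorylation genes against 3, 6 autophagy and lysosome genes against 4, 4 Kupffer cell and macrophage markers against 2, 1 lymphocyte marker against 0 and 1 erythroid marker against 0. The C7 mouse had 1 stellate cell and fibroblast marker against 4. The C8 mouse had 9 insulin and leptin signalling genes against 11 and 1 hepatocyte marker against 0.

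Genes and regions found in every mouse of 1 group and none of the other exceeded the numbers in the other splits. Of the 35 splits of the 8 lists, 1, the real split, gave as many genes (139, highest other 32), and 1 gave as many regions (397, highest other 76). A permutation over 35 splits can give no p under 0.0286, so chance assignment of mice is unlikely as the source of the totals but not excluded. Genes and regions come from the same 8 lists and are not separate tests. A batch that follows the groups is not excluded either, and the labels give no information on one. A transcript absent from the other group is argued against as the whole cause. Of the 397 regions, 15.6% (62, exact 95% interval 12.2 to 19.6%) lay in a gene with another region called in all 8 mice. The lower bound was above the limit of 10% set beforehand. By a looser measure, 166 of the 217 db/db and 137 of the 180 lean regions lay in genes that were not group-specific themselves. A transcript level that differs between groups may contribute. Among genes with a group-specific region whose other regions leaned to either group, these leaned the same way in 67.7%. The share was 74.9% for db/db (125 of 167 genes, 67.6 to 81.2%, against 57.2% in other genes) and 58.1% for lean (72 of 124, 48.9 to 66.9%, against 42.8%). Acetylation that changes along a whole transcript would give the same. The exact intervals for these shares treat genes or regions as independent, although they come from the same 8 lists. They do not measure the spread between mice.

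Most peaks carry a false discovery rate of 100%, and 17905 regions consisted solely of calls with a score under 50. If each mouse's weak calls fell independently and with the same chance in every region, 668 of these regions would be called in 4 or more mice. The number found was 1517, a ratio of 2.27 (exact 95% interval 2.16 to 2.39). The interval treats regions as independent and does not measure the spread between mice. The expectation is from calling rates, 1 per mouse for all regions, fitted to the same regions so that they imply the 30765 calls made. A first version took each mouse's share of the seen regions as its rate and gave a ratio of 1.03, but it implied 35929 calls and was replaced after its result had been seen. Under the fitted rates the ratio argues against independent placement with an equal chance in every region. It cannot decide on independent placement with chances that differ between regions, which would also raise it. Background that recurs for reasons other than acetylation, such as high transcript level, could give the same and was not tested.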

How the results depend on the processing

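The score of at least 50 and all settings for fold, width and named genes were chosen after seeing the data; the other settings were fixed before. The within-group similarity stayed above the between-group similarity in all 7 other settings and with each of the 8 lists left out, at the smallest p the splits allow. No paired analysis was possible because the lean lists C5 to C8 carry no number of the lean titles, and a db/db and a lean list share only the number 5. Position in transcripts and cytidine content were not run for lack of annotation and sequence used here, and deposited rows were already unique peaks. Depth is unknown, so an absent peak limits every count. Stricter rules call fewer peaks and looser ones more, which moves counts by construction; the cause of other changes was not tested.

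Group-specific counts were made anew in each setting, so a gene or region can enter when weaker peaks of the other group are dropped. In the upper part of the pooled score there were 53 db/db-specific and 53 lean-specific genes, and 92 and 98 regions. In that setting 2 lists had an unadjusted p under 0.05 (antioxidant defence and ribosomal proteins). List differences changed sign for cholesterol (-1.25), Kupffer cell (0.25), cholangiocyte (-0.75) and erythroid genes (-0.25). At a fold of at least 4 there were 53 db/db-specific genes and 108 and 84 regions, 1 list had an unadjusted p under 0.05 (ribosomal proteins, as at a score of at least 50), and signs changed for fatty acid uptake (-0.5), fatty acid oxidation (0.25), cholesterol (-1.0), stellate cell (-0.5) and cholangiocyte genes (-0.5). At a score of at least 50 there were 28 and 34 genes and 55 and 60 regions, and signs changed for ac4C writer (-0.5), circadian (-0.5), Kupffer cell (0.75), stellate cell (-0.75) and erythroid genes (-0.25). With equal numbers of peaks the difference in genes per mouse was -21.5, that in median fold 0.15, 0 lists had an unadjusted p under 0.05, and signs changed for cholesterol (-0.5), fibrosis (-0.75), circadian (-0.25) and autophagy genes (-0.25). The ratio of db/db-specific to lean-specific genes fell from 1.4 to 0.83 (58 and 70 genes), and regions numbered 155 and 182, so the longer db/db lists may account for the excess. In at least 3 mice against none there were 298 and 165 genes and 854 and 604 regions.

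Leaving out each list gave differences of 724.4 to 1238 peaks (past the threshold only without db5). Group-specific genes ranged from 103 to 147 and 69 to 103, and regions from 261 to 454 and 216 to 318, since 3 mice meet the rule more easily than 4. Counts over 1.5 times the full ones came without db1 (147 and 88 genes, 454 db/db regions), db2 (133 genes, 339 regions), db4 (330 regions), db5 (146 genes, 381 regions), C6 (288 lean regions), C7 (278) and C8 (103 lean genes, 318 regions). Lists with an unadjusted p under 0.05 numbered 0 (without C7) to 4 (without db1), and 2 without db5 or C5. Differences ranged from -1.58 to 1.08 for fatty acid uptake, -0.917 to 1.75 for cholesterol, -0.167 to 1.5 for insulin signalling, -1.92 to 0.0833 for endoplasmic reticulum stress, -0.833 to 0.25 for Kupffer cell and -0.0833 to 0.917 for cholangiocyte genes.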

Other observations

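The term enrichment, the gene-end comparison with its alternatives and the list of highest folds were chosen after the data had been examined. Genes with a peak in all 8 mice were rich in terms of several kinds, with RNA processing at the top. The spliceosome pathway had 49 of its 99 genes with any peak among them (20.7 from chance, exact hypergeometric test, Benjamini-Hochberg adjusted p = 2.94e-08), and the mRNA surveillance pathway 32 of 63 (13.1 from chance, adjusted p = 1.3e-05). ATP-dependent RNA helicases contributed 27 of 43 genes (8.54 from chance, exact test, adjusted p = 6.15e-07), and the nucleolus 137 of 474 (94.3 from chance, adjusted p = 7.84e-05). Other terms passed too, such as endocytosis (61 of 181 genes, exact test, adjusted p = 0.00169), calcium reabsorption (16 of 28, 0.00169), tight junction (26 of 67, 0.0193) and actin binding (62 of 181, 0.000373). Background genes had a peak in at least 1 mouse, and transcript level was not controlled for. Genes leaning to db/db (616 genes) or to lean (433 genes) had 0 enriched terms after adjustment in any of the categories of terms.

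A larger share of the peaks of lean mice lay near an annotated gene end. In genes of at least 5000 bp, 23.5 ± 1.51% of lean peaks and 20.3 ± 0.749% of db/db peaks fell within 500 bp of either annotated gene end (n = 4 each, exact permutation p = 0.0286, without adjustment). Every lean list (21.6 to 25.2%) was above every db/db list (19.5 to 21.3%). Lean peaks were also wider, with a median of 183 to 195 bp per list against 177 to 180 bp, and wide peaks lay near gene ends more often. The difference of -3.23 percentage points was -3.01 for the middle of each peak. It was -1.79 in peaks up to the median width of all lists and -3.02 in wider peaks (exact permutation p = 0.0571 each). The sign held in every alternative, but the exact permutation p was also 0.0571 at a fold of at least 4, at a score of at least 50, with equal numbers of peaks and whichever db/db list was left out. Of regions called only in lean mice, 48 of 172 lay near a gene end (27.9%), against 38 of 209 (18.2%) for regions called only in db/db mice. Fisher's exact p of 0.0268 for this treats regions as independent, although they come from the same 8 lists, so it is no separate evidence. Strand and exons were not used, so start and end of the transcript were not told apart.

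The highest folds belonged to a small set of genes in both groups. Gm10800 led all 8 lists, with a fold of 3927 to 5054 in db/db and 4123 to 6071 in lean lists. Gm10801 had folds of 780.4 to 1011 and 829.4 to 1270, and Gm4799 of 1018 to 1323 and 620.7 to 720.2. Predicted genes and pseudogenes made up 23.1 to 30.3% of the 1% of peaks with the highest fold and 2.59 to 2.97% of the other peaks. Whether reads from elsewhere in the genome were placed on the genes with the highest folds was not tested. Their folds are therefore uncertain as a measure of acetylation. AA474408 had folds of 359.8 to 476.3 in db/db and 137.1 to 205.9 in lean lists, and these folds were not compared between groups.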
